A study of Mus musculus with 27 samples.

How the data were processed

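Gene expression was measured with Affymetrix mouse genome arrays of 3 types (A, B and C) in 9 RNA samples, which gave 27 arrays. Per the labels, total RNA was prepared with RNeasy from limb bud mesenchymal cells, labelled with biotin and hybridised. The samples fall into 3 groups of 3: multipotential mesenchymal cells, chondroprogenitors harvested at day 1 and chondroblasts harvested at day 3. The replicate numbers are 1, 3 and 4 in every group. Groups and replicates were taken from the sample titles and the labels; the titles of the mesenchymal samples carry no day.

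The deposited values are 1 intensity (the MAS5 signal) per probe set and array, on a linear scale. Per the labels they were made with MAS5; its version and settings are not given in the sources used here. The deposited signals had a 2% trimmed mean of 1501 in each group, so each array had been scaled before deposit. Scanner images and probe-level intensities were not used here. The experiment records of the 27 arrays gave the batches in which arrays were scanned.

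Each array was rescaled to a 2% trimmed mean of 500, and log2 of the rescaled signal plus a pseudocount of 50 was taken. Control probe sets (66 per array) were left out, as were 13156 probe sets whose mean rescaled signal was below 200 in every group. The remaining 23545 probe sets were tested in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with a trend, in 1 fit of all 9 samples per array type and with group means only. Benjamini-Hochberg adjustment ran over the probe sets of all 3 array types together, with a threshold of 0.05. The moderated F test gave the change over the 3 groups. Errors of log2 changes are limma's standard errors, with n = 3 RNA samples per group. A log2 change in which 1 group lies below the filter depends on the pseudocount.

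Gene names came from the platform annotation held by GEO, updated through the Entrez identifier to a reference table of the assembly GRCm38.p6. Of 36701 probe sets, 29131 had 1 gene symbol, 724 had several and 6846 had none, and 29044 symbols were updated through the identifier. Probe sets with several genes name none. A gene was represented by 1 probe set, chosen from array type A before B before C and then by the highest mean signal, which gave 12214 genes. Other probe sets of the genes past the threshold had the same sign as the representative for 377 of 495 at day 1 against mesenchymal cells, 162 of 178 at day 3 against day 1 and 890 of 1135 at day 3 against mesenchymal cells. Of these 131, 42 and 313 passed the threshold in the same direction, and 1, 0 and 11 in the opposite one.

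Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, and the p-values of 26 lists in 3 comparisons (78 tests) were adjusted together. The lists cover cartilage matrix, chondrogenic transcription factors, hypertrophy and ossification, limb patterning transcription factors, FGF and hedgehog signalling, Hox genes, BMP, GDF and TGF-beta signalling, Wnt signalling, retinoid metabolism and signalling, cell cycle, cell adhesion in condensation, fibroblast and connective tissue, tendon and joint, skeletal muscle, endothelium, erythroid cells, macrophage and leukocyte, ectoderm and epithelium, neural and Schwann cells, adipocyte, immediate early genes, heat shock, hypoxia and glycolysis, ER folding and secretion, oxidative phosphorylation, and ribosomal proteins. Some genes sit in more than 1 list, and limb mesenchyme and its derivatives also express members of the lists of other cell types. The lists, the tests, the filter, the threshold, the rule for named genes and most alternatives were fixed before the data were examined.

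Genes are named by a rule. It takes, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose 2 groups of values do not overlap. It adds up to 4 members per list with the smallest adjusted p, and a fixed set of limb and cartilage genes. Fewer were named than the rule allows, with preference for calls that held in all alternatives tried. All values of 1 group lay on one side of all values of the other for each call of a named gene, 68 at day 1 against mesenchymal cells, 58 at day 3 against day 1 and 94 at day 3 against mesenchymal cells.

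The steps were tested on simulated data built from the real means and spreads, in a single run per comparison. In each, 67, 67 and 66 probe sets were changed by 1.5-fold, 2-fold and 4-fold. The adjusted threshold is stricter when so few probe sets change, so the share recovered in the real comparisons may differ. Of changes of 1.5-fold, 2-fold and 4-fold, 2.99%, 16.4% and 56.1% were recovered for day 1 against mesenchymal cells, 2.99%, 17.9% and 62.1% for day 3 against day 1, and 0%, 17.9% and 63.6% for day 3 against mesenchymal cells, over 23545 probe sets. False calls were 7 of 57 (12.3%), 7 of 62 (11.3%) and 2 of 56 (3.57%), so in the first 2 comparisons their share was above the 5% that the threshold aims at. A list of 20 members shifted by 0.5 on the log2 scale among 12214 genes gave p = 1.71e-09 (camera, a test across genes, n = 20 genes) for day 3 against day 1, and 8 of 200 unshifted lists gave a p under 0.05.

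Alternatives tried were quantile scaling, equal medians, signals without rescaling, pseudocounts of 16 and 100, no filter and a filter at 400, other variance priors, array weights, adjustment within each array type, a threshold of 0.01, a test against a 1.5-fold change, fits of only the groups compared, scan batch and replicate number as blocks, each RNA sample left out in turn, and, for lists, an estimated correlation, fry and the mean of all probe sets of a gene. Leaving out the 3 RNA samples with a high 18S signal, the 18S signal as a covariate, scan batch for the lists, and the replicate block on day 1 and day 3 alone were added after the data were seen. List p-values with scan batch as a block came from cameraPR, a form of camera that takes precomputed statistics. It was run on the moderated t values of the blocked probe set fits. RNA quality was described by the 3' over 5' signal ratios of the actin and Gapdh control probe sets, the 18S and spike-in control signals and the share of probe sets below 200, with exact 2-sided permutation tests between groups. The number of arrays limits the precision of every value.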

Results

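Mouse limb bud mesenchymal cells were profiled with Affymetrix arrays as they were allowed to form cartilage cells in culture. The cells came from the subridge region of the limb bud, the tissue beneath its distal ridge, and the labels name fibroblasts as the contaminating cell type. The labels give the same purity range for all 27 arrays. If that range held in every group, the share of these fibroblasts could change only within it. This argues against a changed share as the only cause of large rises. For smaller changes, a changed share of these fibroblasts cannot be told apart here from changed expression in the differentiating cells. Mesenchymal cells, chondroprogenitors at day 1 and chondroblasts at day 3 made 3 groups of 3 RNA samples, each hybridised to 3 array types, for 27 arrays. The labels do not state whether samples came from separate cultures or animals. The limma p-values of probe sets therefore measure only the spread between these samples, which may be technical. The camera p-values of gene lists compare a list's genes with the other genes under an assumed correlation, and do not measure the spread between samples. The study's title names the question, how gene expression changes over time in these differentiating cells, and 3 comparisons between the groups address it.

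Of 36701 probe sets, 23545 passed the signal filter in at least 1 group. Probe sets with a rescaled signal below 200 made up 44.1 ± 1.96% (SD, n = 3) in mesenchymal samples, 47.0 ± 1.29% at day 1 and 46.3 ± 1.17% at day 3. Log2 signals of samples of 1 group correlated across probe sets, which are not independent replicates, at 0.911 to 0.981 on array type A, 0.829 to 0.942 on B and 0.808 to 0.902 on C. The first principal component held 49.4%, 34.3% and 23.6% of the variance on these types. The actin 3' over 5' signal ratio was 1.15 ± 0.114 (SD, n = 3) in mesenchymal samples, 1.10 ± 0.0250 at day 1 and 1.19 ± 0.0996 at day 3. In 3 samples, 1 per group (mesenchymal replicate 1, day 1 replicate 4 and day 3 replicate 4), the 18S control signal was 34315 to 42715.5, against 2071.5 to 10103.5 in the other 6. These 3 also had the highest Gapdh 3' over 5' ratios (1.04, 0.882 and 0.960, against 0.801 to 0.853), and mesenchymal replicate 1 and day 3 replicate 4 the highest actin ratios (1.28 and 1.30). Exact 2-sided permutation tests of 3 against 3 samples cannot give a p below 0.1. Among the RNA quality measures the share of probe sets below 200 reached that floor for day 1 against mesenchymal samples (exact p = 0.1).

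By day 1, 10 of 21 cartilage matrix genes had risen and 7 of 14 endothelial genes had fallen. Cytl1, which encodes a secreted protein of cartilage, rose from a mean rescaled signal of 43.8 to 2167 (log2 change 4.57 ± 0.39, SE, n = 3 per group, limma adjusted p = 4.85e-06). Where 1 group's mean lay below the filter, as here, the log2 change depends on the pseudocount and no fold is given. The matrilin gene Matn4 rose 23.3-fold (4.54 ± 0.25, adjusted p = 9.03e-07), and the collagen genes Col9a1 and Col9a3 rose by 2.84 ± 0.20 and 2.37 ± 0.17 on the log2 scale. The transcription factor genes Sox9 and Sox6, which act in cartilage formation, rose by 1.51 ± 0.19 (adjusted p = 0.000263) and 2.23 ± 0.25 (adjusted p = 0.000248). Cdh5, the cadherin gene of endothelium, fell by 3.03 ± 0.37 (adjusted p = 0.000433) to a mean signal of 16.5. Osr1 (3.80 ± 0.23) and Prss35 (4.01 ± 0.43) were also among the largest rises, and Trim71 (-2.69 ± 0.49) and Zic5 (-2.67 ± 0.43) among the largest falls. Col2a1, Sox5, Col10a1 and Shh lay below the filter, and Cyp26b1 had no probe set of its own. Other probe sets did not pass at day 1 for Sox9 (4 others, 0.10 to 1.34), Matn4 (0.19, adjusted p = 0.856), Cytl1 (0.94, adjusted p = 0.458) and Trim71 (-1.24, adjusted p = 0.329), whereas the other probe sets of Col9a1, Col9a3 and Sox6 rose too (3.18, 3.87 and 3.48).

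Of 23545 probe sets, 1128 changed between mesenchymal cells and day 1, 849 higher and 279 lower, which represent 556 genes that rose and 166 that fell. At an unadjusted p under 0.05 there were 4383. The count was 555 without day 1 replicate 1 and 572 without day 1 replicate 3. With scan batch as a block it was 615, of which 533 were among the 1128. The batches that held both groups had 1, 3 and 3 day 1 samples and 2, 2 and 1 mesenchymal samples on array types A, B and C, so every blocked value on A at day 1 against mesenchymal cells rests on day 1 replicate 1 alone. Within that batch of A, the median log2 difference of the 15 cartilage matrix genes on A was 0.70, against 0.96 over all samples, and that of 10 endothelial genes was -1.93 against -1.77.

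**Figure D1:**
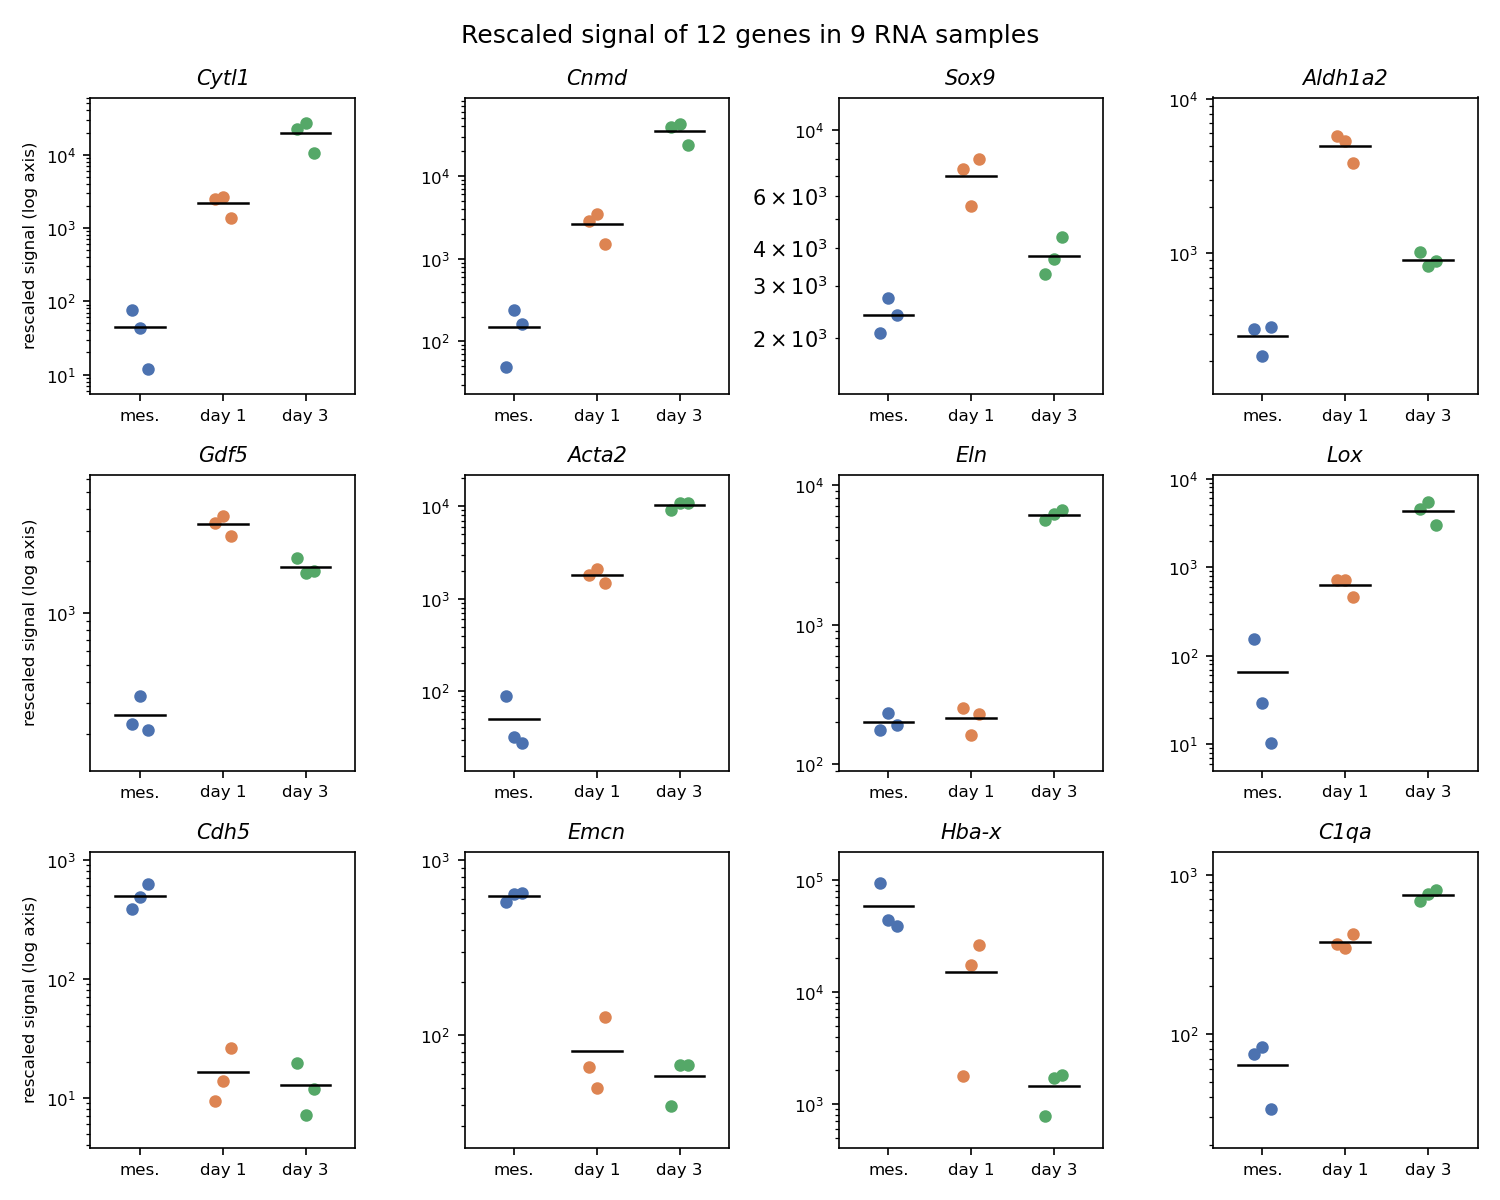
Rescaled signals (log axis) of 12 genes in the 3 groups, with points for the 3 RNA samples of a group and a black line for the mean. Cytl1 rose from a mean of 43.8 to 2167 and 20022, Aldh1a2 was highest at day 1 (4993), and Cdh5 fell from 496.8 to 16.5.

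Cartilage matrix genes rose as a list at day 1. Of 21 measured, 10 rose and 0 fell (also 10 adjusted over the list alone), with a median log2 change of 0.96 (camera adjusted p = 4.08e-09) that was 0.73 with scan batch as a block (adjusted p = 1.91e-13). The blocked list tests were chosen after the data were seen. Here and below they used cameraPR on moderated t values, whereas the unblocked tests used camera on the signals. A smaller blocked p therefore does not mean that blocking strengthened a list, and only the medians can be compared. Of 38 genes of BMP, GDF and TGF-beta signalling, 12 rose and 0 fell (17 and 0 adjusted over the list alone), among them Gdf5 (3.45 ± 0.19), Bmp7 (2.86 ± 0.21) and Tgfb3 (1.28 ± 0.20). The list's median was 0.68 (adjusted p = 3.13e-07), or 0.87 with the block (adjusted p = 4.82e-11). Of 14 retinoid genes, 6 rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.63 (adjusted p = 5.24e-05). The blocked median was 0.89 (adjusted p = 3.71e-10). The enzyme genes Aldh1a2 and Rdh10, which act in the making of retinoic acid, rose 14.7-fold and 8.65-fold, and the receptor gene Rarb rose 7.17-fold. Of Aldh1a2's 2 other probe sets 1 rose by 1.60 and 1 gave -0.39 without passing, whereas both others of Rdh10 rose. Of 36 fibroblast and connective tissue genes, 13 rose and 1 fell (18 and 3 adjusted over the list alone), with a median of 0.53 (adjusted p = 1.18e-06). With the block it was 0.40 (adjusted p = 1.58e-06). Among them Acta2 rose by 4.25 ± 0.23, although its other probe set did not (-0.34, adjusted p = 0.775), and Lox rose by 2.76 ± 0.39. Whether genes of this list rose in the differentiating cells or through more contaminating fibroblasts was not tested, here or in the later comparisons. The purity range in the labels, if it held in every group, limits how much of a large rise more fibroblasts could explain.

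Of 32 Wnt genes, 7 rose and 0 fell at day 1 (9 and 1 adjusted over the list alone), with Ror2 up by 2.54 ± 0.22 and Sfrp2 by 2.29 ± 0.16. The Wnt median was 0.13 (adjusted p = 0.0160, or adjusted p = 0.0706 with an estimated correlation). Its median with scan batch as a block was 0.20 (adjusted p = 0.0285). Of 7 hypertrophy and ossification genes, 2 rose (4 adjusted over the list alone), 1 of them Pth1r by 2.08 ± 0.23, and the median was 1.35 (adjusted p = 0.00130, or adjusted p = 0.0706 with an estimated correlation). Blocked for scan batch, the median was 1.52 (adjusted p = 0.0227). Of 42 cell cycle genes, 6 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.34 (adjusted p = 1.97e-06, or adjusted p = 0.136 with an estimated correlation). After blocking, the list's median was -0.29 (adjusted p = 0.0110). Mki67, a marker of cycling cells, did not pass (-0.14, adjusted p = 0.885). Among 27 limb patterning factors 6 rose and 4 fell (7 and 4 adjusted over the list alone), with Msx1 up by 1.87 ± 0.20 and Hand2 down (-1.65 ± 0.22), and the list as a whole did not pass (adjusted p = 0.220). Prrx1 did not pass (-0.24, adjusted p = 0.687), though another of its probe sets fell by 0.91. Neither did the lists of chondrogenic transcription factors (3 of 13 rose, or 3 rose and 1 fell adjusted over the list alone, adjusted p = 0.0761) or cell adhesion (3 of 21 rose and 2 fell, or 7 and 3 alone, adjusted p = 0.0764). FGF and hedgehog signalling (3 of 25 rose and 3 fell, or 4 and 4 alone, adjusted p = 0.649) and Hox genes (3 of 26 rose, also 3 alone, adjusted p = 0.746) did not pass either. Fgfr2 rose by 2.35 ± 0.19, while only 2 of its 4 other probe sets passed (0.52 to 2.64 over the 4).

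From day 1 to day 3, 12 of 21 cartilage matrix genes and 15 of 36 fibroblast and connective tissue genes rose, and Aldh1a2 and Bmp2 fell. Matn1 rose from a mean signal of 25.7, below the filter, to 1181 (log2 change 4.02 ± 0.34, SE, n = 3 per group, limma adjusted p = 7.05e-05). Cnmd, which encodes chondromodulin, rose by 3.74 ± 0.40 (adjusted p = 8.36e-05) and the aggrecan gene Acan by 1.83 ± 0.26 (adjusted p = 0.00355). The elastin gene Eln rose 23.4-fold (4.55 on the log2 scale, adjusted p = 4.65e-07), and its other probe set rose less (2.44, adjusted p = 0.0149). The largest rises further held Grp (5.39 ± 0.48), Ogn (3.92 ± 0.20) and Aspn (3.76 ± 0.39). Aldh1a2 fell by 2.37 ± 0.21 (adjusted p = 8.36e-05), to a mean of 911.7, and 1 of its 2 other probe sets fell too (-1.60). Bmp2 fell by 2.48 (adjusted p = 0.00541), with its other probe set at -1.98. Sox9, which had risen at day 1, fell by 0.87 ± 0.19 to a mean of 3774.4 (adjusted p = 0.0321), while none of its 4 other probe sets passed (-0.47 to 0.37, lowest adjusted p = 0.654). It is measured on array type B, where scan batch cannot be told apart from these groups, and it had an adjusted p of 0.152 and 0.139 without day 1 replicates 1 and 4, and 0.174 and 0.125 without day 3 replicates 1 and 3. Ror2 fell by 1.26 ± 0.22 (adjusted p = 0.0136, or 0.0616 with scan batch as a block), its 2 other probe sets not passing (-0.88 and -0.47), with an adjusted p of 0.0866 and 0.0537 without day 1 replicates 1 and 3, and 0.0769 and 0.0533 without day 3 replicates 3 and 4. Sfrp2 fell by 0.89 ± 0.16 (adjusted p = 0.0136, or 0.0589 with the block), with an adjusted p of 0.0706 and 0.0806 without day 1 replicates 1 and 3, and 0.0832 and 0.05005 without day 3 replicates 1 and 4. Bmp7 fell by 0.97 ± 0.21 (adjusted p = 0.0384, or 0.137 with the block), its other probe set not passing (-0.78), with an adjusted p of 0.0525 without mesenchymal replicate 3, 0.179 and 0.176 without day 1 replicates 1 and 3, and 0.143, 0.0781 and 0.128 without day 3 replicates 1, 3 and 4. Nnat (-1.97 ± 0.23) and Phlda2 (-1.88 ± 0.18) were also among the largest falls, as was Rasgef1b (-3.11 ± 0.42), whose other probe set did not pass (-0.25, adjusted p = 0.885).

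In this comparison 380 probe sets changed, 266 higher and 114 lower, for 206 genes that rose and 77 that fell, and 2549 had an unadjusted p under 0.05. The count was 189, 190 and 233 without day 1 replicates 1, 3 and 4, and 167 and 181 without day 3 replicates 1 and 3. It was 1131 with array weights. With the replicate number as a block on the day 1 and day 3 samples alone, a fit chosen after the data were seen, it was 1162. With scan batch as a block it was 278, of which 257 were among the 380. On array type A, 1 batch held 3 day 3 and 2 day 1 samples, and within it the median difference of the 15 cartilage matrix genes was 1.37, against 1.33 over all samples. On C all 6 samples were of 1 batch. On B each of the 2 groups lay in a batch of its own, so there scan batch and group cannot be told apart, and the block, there a random effect, does not remove it.

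Matrix, secretory and adhesion lists rose from day 1 to day 3. Of 21 cartilage matrix genes, 12 rose (16 adjusted over the list alone) with a median of 1.58 (adjusted p = 2.95e-21). The blocked median was 1.58 (adjusted p = 4.24e-39). Of 36 fibroblast and connective tissue genes, 15 rose (25 adjusted over the list alone), among them Postn by 3.02 ± 0.26 and Ccn2 by 2.52 ± 0.18, with a median of 1.02 (adjusted p = 4.96e-29). With the block it was 1.07 (adjusted p = 7.64e-54). Of 28 genes of ER folding and secretion, 4 rose (10 adjusted over the list alone), with Kdelr3 up by 1.87 ± 0.20 and a median of 0.51 (adjusted p = 3.59e-09). Its median with scan batch as a block was 0.52 (adjusted p = 1.62e-10). Of 21 cell adhesion genes, 2 rose (5, and 1 lower, adjusted over the list alone), with Tnc up by 2.06 ± 0.26 while its other probe set did not pass (1.43, adjusted p = 0.143). That list's median was 0.50 (adjusted p = 0.000252). Blocked for scan batch, the median was 0.56 (adjusted p = 2.43e-05). Of 28 hypoxia and glycolysis genes, 6 rose (8 adjusted over the list alone), with a median of 0.43 (adjusted p = 3.57e-07, or adjusted p = 0.0706 with an estimated correlation). After blocking, the list's median was 0.55 (adjusted p = 7.17e-08).

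Limb patterning factors fell as a list at this step. Of 27, 2 fell and 0 rose (7 and 1 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.000561). The blocked median was -0.45 (adjusted p = 0.000423). Of 26 Hox genes 2 fell, also 2 adjusted over the list alone, with a median of -0.42 (adjusted p = 0.00322, or adjusted p = 0.195 with an estimated correlation). With the block it was -0.35 (adjusted p = 0.00286). Of 42 cell cycle genes 2 fell (8 adjusted over the list alone), with a median of -0.29 (adjusted p = 2.37e-05, or adjusted p = 0.178 with an estimated correlation). Its median with scan batch as a block was -0.24 (adjusted p = 0.000353). The signalling lists held genes going both ways: 3 rose and 3 fell for BMP, GDF and TGF-beta (5 and 5 adjusted over the list alone; median -0.09, but mean 0.01 and test upward, adjusted p = 0.971), 2 and 4 for Wnt (4 and 4 alone; 0.810), and 1 and 2 for retinoid genes (2 and 2 alone; 0.359). Chondrogenic transcription factors (1 rose, 1 fell; 1 and 2 alone; 0.310), FGF and hedgehog signalling (1 rose; 1 and 1 alone; 0.587) and hypertrophy and ossification (0; 1 alone; 0.689) did not pass either.

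Between mesenchymal cells and day 3, the span of the time course, Cytl1 rose by 7.70 ± 0.39 on the log2 scale (SE, n = 3 per group, limma adjusted p = 1.12e-08) and Cnmd by 7.53 ± 0.40 (adjusted p = 1.63e-08), from mean signals below the filter (43.8 and 151.5) to 20022 and 35032. The other probe set of Cytl1 rose far less (2.40, limma adjusted p = 0.0215). Acta2, the smooth muscle actin gene, rose by 6.73 ± 0.23 (adjusted p = 9.47e-09), with its other probe set at 0.64 (adjusted p = 0.476), and Ogn rose by 6.07 ± 0.20 and Mgp by 5.47. Acan rose by 2.40 ± 0.26 and Col1a1 by 4.05 ± 0.23, with the other probe set of Col1a1 at 2.68. Sall4 fell by 2.81 ± 0.35 (adjusted p = 0.000254), with 1 of its 2 other probe sets down as well (-2.96), and Hand2 fell by 2.54 ± 0.22. The replication gene Cdt1 fell by 1.47 ± 0.15 (adjusted p = 4.86e-05), and so did 1 of its 2 other probe sets.

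Here 2489 probe sets changed, 1541 higher and 948 lower, for 1059 genes that rose and 586 that fell, and 5773 had an unadjusted p under 0.05. The count was 1476 without day 3 replicate 1 and 1485 without day 3 replicate 3. With scan batch as a block it was 1143, of which 1077 were among the 2489. No batch held both groups on array types A or B. On A the blocked values rest on day 1 as the link, and on B, where day 3 shared a batch with neither group, the block was a random effect and scan batch is not removed. On C, 1 batch held 3 day 3 samples and 1 mesenchymal sample, and within it the median difference of 4 cartilage matrix genes was 4.81, against 5.42 over all samples. The median log2 change of all probe sets tested on array type A was -0.12, and that of all 12214 genes -0.05; relative to the latter the cartilage matrix median was 3.16 and the cell cycle median -0.59.

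Of 21 cartilage matrix genes, 17 rose by day 3 (19 adjusted over the list alone) with a median of 3.11 (adjusted p = 1.36e-20). Blocked for scan batch, the median was 2.91 (adjusted p = 3.39e-33). Of 36 fibroblast and connective tissue genes, 28 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 1.67 (adjusted p = 2.12e-21). After blocking, the list's median was 1.35 (adjusted p = 2.62e-27). Of 21 cell adhesion genes, 10 rose and 1 fell (12 and 3 alone), with a median of 0.89 (adjusted p = 0.00108). The blocked median was 0.89 (adjusted p = 0.000423). Of 28 ER folding and secretion genes, 11 rose (13 alone), with a median of 0.51 (adjusted p = 1.78e-06). With the block it was 0.63 (adjusted p = 3.16e-08). Of 42 cell cycle genes, 19 fell and 0 rose (25 and 0 alone), with a median of -0.65 (adjusted p = 2.01e-10, or adjusted p = 0.0706 with an estimated correlation). Its median with scan batch as a block was -0.53 (adjusted p = 0.000171).

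Of 38 genes of BMP, GDF and TGF-beta signalling, 15 rose and 0 fell between mesenchymal cells and day 3 (17 and 5 adjusted over the list alone), with Gdf5 up by 2.65 ± 0.19 and a median of 0.51 (adjusted p = 4.37e-05, or adjusted p = 0.0706 with an estimated correlation). Blocked for scan batch, the median was 0.80 (adjusted p = 9.60e-07). Of 14 retinoid genes 6 rose and 2 fell, the same alone, with Rdh10 up 10.8-fold, Rarb 4.77-fold and Aldh1a2 2.84-fold, though neither of Aldh1a2's other probe sets passed (-0.76 and 0.00). The retinoid median was 0.51 (adjusted p = 0.00647, or adjusted p = 0.0706 with an estimated correlation). After blocking, the list's median was 0.60 (adjusted p = 4.01e-06). Of 7 tendon and joint genes 5 rose, also 5 alone, with Osr1 up by 3.03 ± 0.23 and a median of 2.12 (adjusted p = 4.97e-05, or adjusted p = 0.0706 with an estimated correlation). The blocked median was 1.60 (adjusted p = 4.01e-06). At day 1 that list had 2 that rose (2 and 1 lower alone) and did not pass (adjusted p = 0.0681), but with the block it passed upward (adjusted p = 1.71e-05) although its median was -0.10, and from day 1 to day 3 it had 1 (4 and 2 lower alone; 0.0597).

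Further lists passed at day 3 against mesenchymal cells with the preset correlation alone. Of 13 chondrogenic transcription factors 6 rose, also 6 adjusted over the list alone, with a median of 0.64 (adjusted p = 0.0108, or adjusted p = 0.136 with an estimated correlation), or 0.64 (adjusted p = 0.0623) with the block, and Creb3l2 rose by 1.65 ± 0.26. Of 7 hypertrophy and ossification genes 3 rose (5 alone), with a median of 0.94 (adjusted p = 0.00423, or adjusted p = 0.0915 with an estimated correlation). With the block it was 1.05 (adjusted p = 0.0741). Of 32 Wnt genes 9 rose and 2 fell (12 and 5 alone), with Dkk3 up by 3.27 ± 0.23 and a median of 0.35 (adjusted p = 0.0488, or adjusted p = 0.120 with an estimated correlation). Its median with scan batch as a block was 0.32 (adjusted p = 0.201). The Wnt list had an adjusted p of 0.0564 without mesenchymal replicate 1, 0.0592 without mesenchymal replicate 3, and 0.0604 and 0.0810 without day 3 replicates 3 and 4. Of 26 Hox genes 1 fell, also 1 alone, with a median of -0.45 (adjusted p = 0.0211, or adjusted p = 0.285 with an estimated correlation), or -0.51 (adjusted p = 0.0741) with the block, and its adjusted p was 0.0559 without mesenchymal replicate 1, and 0.0602 and 0.0604 without day 3 replicates 1 and 3. Limb patterning (4 of 27 rose and 6 fell; 5 and 9 alone; adjusted p = 0.310) and FGF and hedgehog signalling (5 of 25 rose; 5 alone; median -0.11, but mean 0.03 and test upward; 0.865) did not pass.

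**Figure D2:**
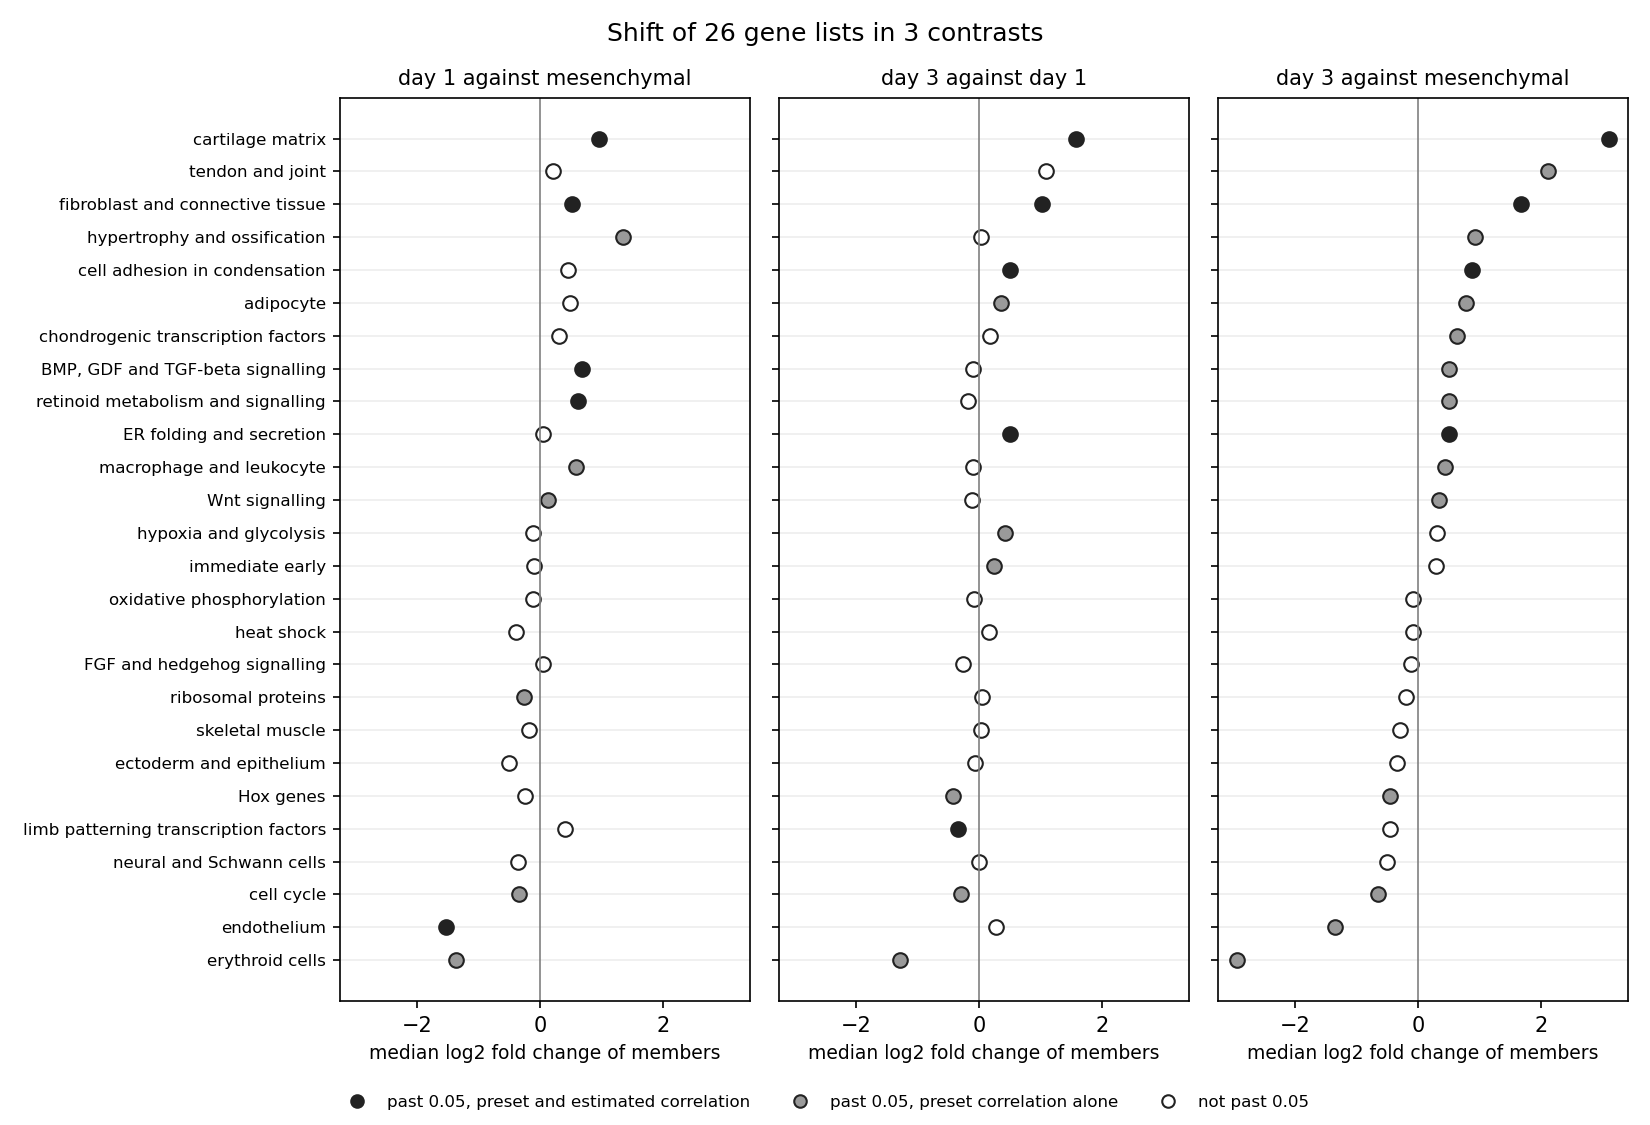
Median log2 change of the 26 gene lists in the 3 comparisons, with black points for lists past 0.05 with both the preset and an estimated correlation, grey for the preset alone and white for neither. The cartilage matrix list is black in all 3 comparisons, with medians of 0.96, 1.58 and 3.11.

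With an estimated correlation, 14 of the 38 list calls held: cartilage matrix and fibroblast and connective tissue in all 3 comparisons; BMP, GDF and TGF-beta signalling, retinoid genes and endothelium at day 1 against mesenchymal cells; limb patterning factors at day 3 against day 1; and cell adhesion and ER folding and secretion at day 3 against both other groups. In that order their adjusted p with an estimated correlation was 0.0412, 0.0143 and 0.0143 for cartilage matrix, 0.0239, 0.00178 and 0.00221 for fibroblast genes, 0.0428, 0.0317, 0.0264 and 0.0412 for the next 4, 0.0375 and 0.0428 for cell adhesion and 0.0192 and 0.0317 for ER folding.

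Of 14 endothelial genes, 7 fell and 0 rose at day 1 (11 and 0 adjusted over the list alone), with a median of -1.53 (adjusted p = 3.40e-09), or -1.60 (adjusted p = 6.15e-09) with the block, and Emcn fell by 2.40 ± 0.31, its other probe set by 2.22. From day 1 to day 3, 1 rose (2 alone; adjusted p = 0.0665), and at day 3 against mesenchymal cells 7 fell and 1 rose (8 and 1 alone), with a median of -1.34 (adjusted p = 0.000252, or adjusted p = 0.0706 with an estimated correlation). Blocked for scan batch, the median was -1.47 (adjusted p = 0.00153). Of 11 erythroid genes, 9 fell between mesenchymal cells and day 3 (10 alone), with a median of -2.94 (adjusted p = 3.33e-07, or adjusted p = 0.160 with an estimated correlation). After blocking, the list's median was -4.93. On array type A that value joins day 1 replicate 1 against mesenchymal samples with day 3 against day 1 replicates 3 and 4. The mean marker level was 8.47 in day 1 replicate 1, against 10.1 and 10.6 in replicates 3 and 4. The blocked median is therefore no direct measure of the difference between day 3 and mesenchymal samples. Alas2 fell by 3.76 ± 0.72 (adjusted p = 0.00519) and Car2 by 2.94 ± 0.43 (adjusted p = 0.000863). Globin genes share sequence, so their separate levels are uncertain; Hba-x fell by 5.28 ± 0.77 over the same span, and its signal at day 1 was 1768 in replicate 1 against 17282 and 26028 in replicates 3 and 4. At day 1, 1 erythroid gene fell (8 alone; median -1.36, adjusted p = 5.17e-05, or adjusted p = 0.245 with an estimated correlation), and from day 1 to day 3, 0 changed (5 fell alone; median -1.28, adjusted p = 0.000133, or adjusted p = 0.270 with an estimated correlation). With the block these medians were -3.05 (adjusted p = 3.04e-21) and -2.13 (adjusted p = 3.72e-22), of which the former compares only day 1 replicate 1 with mesenchymal samples on array type A.

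Macrophage genes went the other way in part. Of 13, 2 rose at day 1 (5 adjusted over the list alone) and 5 by day 3 (5 alone), C1qa by 1.94 ± 0.25 and 2.83 ± 0.25 (adjusted p = 1.37e-05) and Lyz2 by 2.92 ± 0.30 at day 3. The list's medians were 0.58 (adjusted p = 0.0203) and 0.45 (adjusted p = 0.01999), with adjusted p = 0.352 with an estimated correlation for both, and 0.22 (adjusted p = 0.658) and 0.03 (adjusted p = 0.559) with scan batch as a block. The day 1 value had an adjusted p of 0.192 without mesenchymal replicate 4 and 0.101 without day 1 replicate 4, and the day 3 value 0.134 without mesenchymal replicate 4 and 0.0760 without day 3 replicate 4. From day 1 to day 3, 1 rose (2 alone; median -0.10, but mean 0.20 and test upward, adjusted p = 0.179). Of 8 adipocyte genes 0, 1 and 2 rose in the comparisons of day 1 with mesenchymal cells, day 3 with day 1 and day 3 with mesenchymal cells (3, 1 and 3 alone). The adipocyte list did not pass in the first (adjusted p = 0.0700) and passed in the others with medians of 0.37 (adjusted p = 0.0251, or adjusted p = 0.120 with an estimated correlation; 0.0570 with the block) and 0.78 (adjusted p = 0.00587, or adjusted p = 0.0706 with an estimated correlation; 0.0741 with the block), and Cebpb, also expressed outside fat, rose by 1.77 ± 0.27 from day 1 to day 3. The earlier of these calls had an adjusted p of 0.0508 without day 1 replicate 1, 0.0636 without day 1 replicate 3 and 0.0810 without day 3 replicate 4.

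The lists of muscle, epithelium and nerve markers did not pass in any comparison, but 2 of them did at day 1 with scan batch as a block. In the same order of comparisons, 0, 0 and 1 of 16 skeletal muscle genes rose and 0 fell (0, 0 and 1 adjusted over the list alone; adjusted p = 0.505, 0.523 and 0.887). Of 17 ectoderm and epithelium genes 1, 1 and 1 rose and 0, 0 and 1 fell (the same alone; 0.0627, 0.929 and 0.0721), with Krt19 up by 3.23 ± 0.36 between mesenchymal cells and day 3. Of 12 neural and Schwann cell genes 1, 1 and 1 rose and 0, 0 and 3 fell (1, 1 and 1 rose and 2, 1 and 3 fell alone; 0.523, 0.929 and 0.346), the one that rose being Pmp22, by 1.91 ± 0.24 at day 1. With the block, the muscle list was lower at day 1 (median -0.49 against -0.17, adjusted p = 0.0319), as was the ectoderm and epithelium list (-0.67 against -0.51, adjusted p = 0.0469). On array type A these blocked values compare only day 1 replicate 1 with mesenchymal samples.

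Of 21 ribosomal protein genes 0 passed in any comparison, over all genes or adjusted over the list alone, but the list was lower at day 1 (median -0.25, adjusted p = 0.00962, or adjusted p = 0.189 with an estimated correlation; -0.23 and 0.0550 with scan batch as a block; -0.07 and 0.372 with quantile scaling). Its other values were 0.05 at day 3 against day 1 (adjusted p = 0.580) and -0.19 at day 3 against mesenchymal cells (0.0768). Of 28 oxidative phosphorylation genes 0, 0 and 2 rose and 1, 0 and 1 fell (the same alone; adjusted p = 0.297, 0.984 and 0.415), and from day 1 to day 3 their median was -0.07 and their mean -0.02 while camera gave upward. Of 14 heat shock genes 1 fell at day 1 and 1 by day 3 (1 rose and 5 fell at day 1 alone, and 1 fell by day 3), and none of the 3 tests passed (0.0700, 0.0938 and 0.683). Of 20 immediate early genes 1, 1 and 6 rose and 1, 0 and 1 fell (2, 5 and 6 rose and 1, 0 and 2 fell alone; adjusted p = 0.777, 0.0284 and 0.169), and the median at day 1 was -0.10 and the test downward, with a mean of 0.03. The call from day 1 to day 3 had adjusted p = 0.112 with an estimated correlation and adjusted p = 0.0606 with the block, 0.0630 without day 1 replicate 1 and 0.0724 without day 3 replicate 3. Hypoxia and glycolysis genes (0 rose and 2 fell, then 4 rose; 2 and 3, then 6 and 1 alone) did not pass at day 1 (0.0822) or day 3 (0.0560) against mesenchymal cells, and neither did ER folding at day 1 (5 of 28 rose; 6 and 1 lower alone; median 0.06; 0.0700). With the block the ER folding list passed at day 1 (median 0.33, adjusted p = 0.0205).

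Over the 3 groups, 2107 probe sets changed by the moderated F test, for 1403 genes, and the count was 1352 without day 3 replicate 1, 1386 without day 3 replicate 3 and 1093 with scan batch as a block. In both steps of the time course 131 probe sets passed. Of these 83, for 61 genes, rose in both, such as Cytl1, Cnmd, Acta2, Lox and Postn. The other probe sets of Cytl1 and Acta2 passed in neither step. A further 37, for 24 genes, rose and then fell, such as Aldh1a2. Another 7 fell in both and 4 fell and then rose. Independent lists of these sizes would share 9.59, 4.11, 1.35 and 3.15 probe sets, and in 20 simulations of unchanged groups the highest number was 0, but neither value allows for both the effects and the shared day 1 samples. The 131 became 52, 64 and 79 without day 1 replicates 1, 3 and 4, and 55 and 64 without day 3 replicates 1 and 3. Because both steps use the day 1 samples with opposite signs, log2 changes of unchanged groups correlated at -0.500 (-0.511 to -0.490) across probe sets, against -0.165 observed. The covariance was -0.0537 against -0.0779 simulated, a difference of 0.0242.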

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

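The 18S covariate, the fit without the 3 high-18S samples, scan batch as a block for the gene lists and the block on day 1 and day 3 alone were tests chosen only after the results were seen, and the others were planned. Of 327 pairs of a named gene and a comparison, 220 passed, 135 of them in all 23 alternatives run for genes, and 0 reversed. Genes were named with preference for calls that held, so these counts do not stand for all calls. Over all probe sets called, scan batch as a block kept 47.3%, 67.6% and 43.3% in the 3 comparisons, with 0 called in the opposite direction. Of 78 list tests 38 passed, and 14 did in all 17 alternatives run for lists, with 0 reversed. Most gene calls were lost with scan batch as a block (63), without day 1 replicate 1 (38) and without day 3 replicate 1 (37), and most list calls with an estimated correlation (24).

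In the order of day 1 against mesenchymal cells, day 3 against day 1, day 3 against mesenchymal cells and the F test, the counts of 1128, 380, 2489 and 2107 became 2005, 1131, 4246 and 3957 with array weights. With scan batch as a block they were 615, 278, 1143 and 1093. Tests against a 1.5-fold change left 254, 85 and 624, by construction fewer. With the 18S covariate they were 1762, 698, 3685 and 3300. The balance of directions moved too. Of the calls at day 3 against mesenchymal cells 61.9% were higher, against 53.6% with array weights, 71.5% with scan batch as a block and 81.9% in the test against a 1.5-fold change. At a threshold of 0.01 the 131 probe sets called in both steps became 45, by construction. Leaving out 1 RNA sample gave 555 to 1243, 167 to 438, 1476 to 2557 and 1352 to 2040, and 52 to 147 for both steps; part of this comes from fewer samples, and a group left with 2 is assumed to vary like the others. Apart from these, the cause was not tested. Without the 3 high-18S samples the counts were 1099, 263, 2352 and 1956. Quantile scaling, equal medians, the pseudocounts, the filters, the variance priors, adjustment within array types and fits of only the groups compared kept each count within 1.5 times. Leaving out the rescaling moves nothing by construction, since the deposited arrays were already scaled alike.

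With the replicate number as a replicate block the counts were 911, 258, 1998 and 1678, of which 874, 250 and 1954 were among the calls of the 3 comparisons. The labels do not tie the numbers together. Samples of the same number had residual correlations of -0.50 to 0.48 on array type A, -0.18 to 0.21 on B and -0.14 to 0.19 on C, with 3, 2 and 2 of 9 pairs over 0.1. Of the 9 samples 0, 0 and 3 correlated best with their own number in both other groups at once. Between day 1 and day 3 all pairs of the same number were positive: 0.298, 0.329 and 0.479 on A for replicates 1, 3 and 4, 0.104, 0.0287 and 0.210 on B, and 0.0558, 0.127 and 0.190 on C. On A and C each exceeded the pairs of unlike numbers, on B only that of replicate 4 did, whose 2 samples are both high in 18S. The 258 comes from a block over all 9 samples. With only the day 1 and day 3 samples in the fit, 1162 probe sets changed with the block, the 380 among them, and 477 without it. A pairing of day 1 with day 3 is left open, and what these samples share was not tested.

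In every group 13156 probe sets lay below the filter, among them those of Col2a1 and Sox5. Whether their transcripts were scarce or their probe sets read them poorly was not tested.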

Other observations

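Tests on the 18S samples, the cell type markers, the retinoid genes, the gene lists and the number of probe sets called in both steps were chosen only after those results were seen; the counts of other sample splits for the 3 comparisons and for the F test were planned.

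The 3 RNA samples with a high 18S signal deviated together from their group means, with residual correlations of 0.316 to 0.479 on array type A, 0.169 to 0.260 on B and 0.142 to 0.197 on C, while the highest with another sample was 0.234, -0.0425 and -0.0497. Scan batch argues against itself as the cause, since on 0 array types did the 3 samples share a scan batch without others. A candidate explanation is weaker specific signal on the arrays of these samples: their dim probe sets deviated upward against bright ones by 0.182, the highest being 0.132 among the 26 other sets of 1 sample per group, so 1 of 27 sets reached it; their higher 3' over 5' ratios leave RNA quality open as well, which was not tested as a cause. Cells of another type in these samples stay open, as 0 of 9 marker lists of other cell types deviated in all 3 samples beyond expression-matched random lists, which excludes no cell type outside those lists. The 3 samples come from all 3 groups, so the design names no biological difference to test.

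Endothelial markers fell by day 1. Scan batch alone does not account for this in the 3 genes on array type B, whose median difference was -1.55 within a batch of 3 day 1 and 2 mesenchymal samples, but for the 10 genes on A (-1.93) it stays open, as that batch holds 1 day 1 sample. An equal fall of all other cell types at day 1 is argued against by the macrophage markers. Their mean log2 level was 8.53 to 8.93 at day 1 and 7.85 to 8.47 in mesenchymal samples. Medians of the erythroid, ectoderm, neural and muscle lists were below 0 (-1.36, -0.51, -0.36 and -0.17), those of fibroblast, tendon and adipocyte genes above 0. A lower share of some other cell types therefore stays open. The macrophage mean minus the endothelial mean was 1.10 ± 0.0781 (SD, n = 3) at day 1 and -0.848 ± 0.255 in mesenchymal samples. This difference of 1.94 includes the endothelial fall itself. Loss of endothelial cells in culture may explain the fall, but lower transcription in cells that stay cannot be told apart from it, because the members' log2 changes spread by a standard deviation of 0.857, which both allow. For erythroid markers, the difference between day 3 and 2 day 1 samples within the scan batch of array type A that held both days was -2.18, so scan batch does not account for that difference, but over all samples the same members' median was -1.41, 0 erythroid genes passed, and the list's adjusted p was 0.270 with an estimated correlation. Day 1 replicate 1, scanned in another batch, had a mean marker level of 8.47, among those of day 3 (8.14 to 8.68), so a fall from day 1 to day 3 is not settled, and loss of blood cells in culture was not tested further.

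Aldh1a2, Rdh10 and Rarb were higher at day 1 than in mesenchymal cells, and Aldh1a2 was lower again at day 3. Scan batch is argued against for the fall of Aldh1a2, which was -2.26 with scan batch as a block (adjusted p = 0.000804), but not for its rise, as the blocked value of 4.21 (adjusted p = 5.30e-05) rests on 1 day 1 sample. A higher retinoic acid response at day 1 might accompany these genes. Of 11 measured genes that respond to retinoic acid, 3 rose at day 1 and 0 fell. The 3 that rose (log2 changes of 2.85, 1.69 and 0.82) are among 4 that are members of the retinoid list itself. Rarb, also of that list, was not among the 11. The 7 others, most of them Hox genes, had log2 changes of -0.67 to 0.51, of which 0 passed. Their median of -0.30 was not above that of random sets of as many genes, which are not independent (1-sided permutation p = 0.898), and so few genes leave the response open.

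Other splits of the same samples were counted. For the comparisons, each has 10 splits, too few for a share under 0.05. The real split gave 1128, 380 and 2489 changed probe sets, and the highest other split gave 1, 0 and 0. For the gene lists, adjusted within a comparison, the real split gave 11, 11 and 17 lists and the highest other 10, 9 and 9. In each of these 6 counts 1 split, the real one, reached the real value. For the F test, 1 of 100 splits of the 9 samples, the real one, gave 2107 changed probe sets, the highest other being 959. A random grouping of these 9 samples is thus excluded at 0.05. The splits do not reach beyond these samples, which may not be independent. They also cannot speak to scan batch, which follows the groups in part. For probe sets called in both steps, 3 of 100 ordered splits reached the real 131, the real one among them. The other 2 gave 706 and 575, several times the real count, and both set the 3 mesenchymal samples as the middle group against mixtures of day 1 and day 3 samples. This points to a structure of the samples, the distance of mesenchymal cells from both the day 1 and the day 3 group, so the count of splits does not speak for the 2 steps of the time course.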
